A study of Mus musculus with 2 samples.

How the data were processed

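MicroRNA-seq libraries were made from total RNA of the neural tube of mouse embryos of the strain B6NCrl at embryonic day 14.5, per the labels. Both samples belong to 1 group and differ in dam: replicate 1 is pup 1 of dam 1 and replicate 2 is pup 1 of dam 2, collected on the same day. The labels name a single neural tube for each sample and also give the sex as male and female pooled, and the data used here do not settle which holds. A size range below 30 is stated without a unit. No use of molecular identifiers is stated, so reads are not counted as independent molecules, and limits and intervals of ratios and shares cover counting error only.

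The deposited values are raw read counts per gene, 1 table per library, with no header and no normalization. Per the text notes deposited with each library, the counts derive from alignments to the mouse assembly mm10 and the gene annotation M4. The aligner, its version, adapter trimming and read filters are not given in the sources used here. Each table held 1973 miRNA genes and 3 columns of counts, for reads on either strand, on the sense strand and on the other strand. It also held 4 rows that name no gene. Those rows stayed out of library sizes and tests. Reads at several positions took 32.4% of the reads of replicate 1 and 33.3% of those of replicate 2, unmapped reads 11.5% and 11.8%, reads not on the sense strand of any of these genes, other-strand reads included, 2.75% and 3.01%, and ambiguous reads 0% in each. A read at several positions is counted for no gene, so genes with near-identical copies lose reads that a gene with a unique sequence keeps.

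The sense-strand column was used throughout. It held 3172235 counts in replicate 1 and 3671915 in replicate 2, and the other-strand column held 1.26% and 1.49% of the counts on miRNA genes. CPM is a gene's count per 1000000 of these sense counts, computed here. Gene symbols, positions and surrounding genes came from the GENCODE M21 annotation of GRCm38, the same assembly as mm10, by matching Ensembl identifiers without their version. Of the 1973 identifiers, 1894 matched, and the 79 others held 1 read in each library. Positions are counted from 1. An intron or exon is named where another gene on the same strand overlaps the miRNA gene.

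The gene lists, the tests of the report and all but 2 of the alternatives were fixed before the data were examined, while most tests of explanations in the closing section were set later. The 22 lists named 272 miRNA genes of neural, imprinted, Hox and other families and of cell types that a dissected neural tube could carry along. Of these, 258 had a value, and the other 14 were not analysed here, among them Mirlet7e, Mir9-1, Mir142 and Mir126b. Genes named in the text were the 20 with the highest mean CPM, up to 4 members of each list with the highest mean CPM, and, among genes with at least 100 counts over both libraries, the 5 with the highest and the 5 with the lowest ratio between the libraries. The rule gave 93 genes, and any gene outside it is said to have been chosen after its values were seen.

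A gene was called detected with at least 10 counts in both libraries and was tested with at least 10 counts in 1 library or more. Libraries were scaled by the trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3, and log2 ratios are replicate 1 over replicate 2 with a prior count of 0.5. Each of 360 genes was compared by a two-sided exact binomial test of its counts against the scaled library sizes in scipy 1.17.1, with Benjamini-Hochberg adjustment, an adjusted p below 0.05 and a 2-fold minimum. With 1 library per dam no residual degrees of freedom were left for edgeR's quasi-likelihood test, so p-values cover counting error between these libraries and say nothing of the spread between litters. Intervals of ratios and of shares are exact 95% binomial intervals, and the limit set by a count of 0 is that of 3 counts. Each list with at least 3 tested members was described by the percentile of its median log2 ratio among 10000 random lists, drawn gene by gene from the 30 genes closest in mean expression. The plan named detected members for this step, whereas tested members were used, which keeps genes that were low in 1 library. Such lists treat genes as independent, whereas clustered miRNA genes share transcripts. The spread between the libraries was estimated as edgeR's common dispersion, and sampling noise by a chi-square over genes detected in both. Correlations used log2(CPM + 1), with CPM taken there from the TMM-scaled library sizes. The 95% interval of Pearson's r, by Fisher's transformation, treats genes as independent. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for tables and matplotlib 3.10.9 for figures.

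The procedures were tested on simulated data with the real means and library sizes. In a simulated comparison of replicate 1 with replicate 2 over 370 genes, 53 of 57 genes planted with a log2 change of 1.5 were called (93.0%), as were 57 of 59 with a change of 3 (96.6%), and 0 of 254 unchanged genes were. These simulated counts carried counting noise only, which is what the test assumes. They therefore say nothing of how often variation between libraries beyond counting noise leads to a call. A planted coefficient of variation of 30% was recovered as 30.3% over 332 genes. Of 100 null lists of 10 genes, 5 lay outside the middle 95%. These lists were drawn at random with independent noise for each gene. They therefore do not give the rate for lists of clustered genes.

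Alternatives were the either-strand counts, gene copies summed, other count minimums, thinning to the smaller library, DESeq2 1.42.0 size factors, scaling by total counts, other pseudocounts and prior counts, other fold minimums, an assumed coefficient of variation of 0.2 in edgeR's exact test, a denominator without Mir10b, and either library alone. After the data were seen, 2 alternatives were added. In 1 of them other-strand reads were given to the miRNA gene annotated opposite, and in the other list medians used members detected in both libraries.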

Results

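MicroRNA sequencing measured the small RNAs of the neural tube, the embryonic tissue from which the brain and spinal cord form, in B6NCrl mouse embryos at embryonic day 14.5. The 2 libraries made up 1 group. Replicate 1 came from a pup of dam 1 and replicate 2 from a pup of dam 2. The design held no second tissue, age or treatment, so the questions it could address were which miRNA genes the tissue expressed and how far the libraries of 2 litters differed. The count tables held 5941830 reads for replicate 1 and 7074029 reads for replicate 2. Of these, 3172235 reads (53.4%, exact 95% interval 53.3 to 53.4) and 3671915 reads (51.9%, exact 95% interval 51.9 to 51.9) lay on the sense strand of miRNA genes. Abundance is given as counts per 1000000 miRNA-gene counts (CPM) or as a percent of them, as the mean ± SD over both libraries (n = 2) unless stated. A count of 0 allowed up to 0.946 CPM in replicate 1 and 0.817 CPM in replicate 2. Intervals of shares and ratios and these limits cover counting error only. Positions are on GRCm38, the build that is also called mm10.

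MiRNA genes of the Hox clusters, which share loci with the transcription factor genes that pattern the body axis, made up 39.5% ± 3.53 (SD, n = 2) of all miRNA counts, and 6 of 6 were detected. Reads at several positions, 32.8% ± 0.648 of all reads, entered no gene count, so shares and ranks here describe reads at single positions. On this measure Mir10b was the most abundant gene, at 216129 ± 30061 CPM. It lies at chromosome 2, 74726070 to 74726137, in an intron of Hoxd3 and Hoxd4. Mir10a followed at 163731 ± 2866 CPM, at chromosome 11, 96317165 to 96317274, outside any other annotated gene of its strand. Mir615, in an intron of Hoxc5 at chromosome 15, 103014910 to 103015001, reached 9643 ± 420 CPM. Mir196b, in an exon of Hoxa9 at chromosome 6, 52230081 to 52230165, reached 4044 ± 1275 CPM. Close relatives of the miR-10 sequence ranked high as well. Mir99a, in an intron of the noncoding host gene Mir99ahg at chromosome 16, 77598936 to 77599000, had 148255 ± 1954 CPM. Mir100, at chromosome 9, 41531425 to 41531504, had 33699 ± 670 CPM, and Mir99b, in an intron of Spaca6 at chromosome 17, 17830188 to 17830257, had 17360 ± 386 CPM.

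The let-7 family, which rises as tissues differentiate, took 5.99% ± 0.920 of counts, with 10 of the 10 measured members detected. Mirlet7g, in an intron of Wdr82 at chromosome 9, 106178840 to 106178927, was its highest member by reads at single positions, at 25797 ± 3542 CPM. Members with near-identical copies lost the reads that fitted several positions, so their place in this order is uncertain and the family's share may be understated. Mirlet7i, at chromosome 10, 122985640 to 122985724, stood at 21359 ± 3675 CPM, while Mirlet7b reached 6005 ± 302 CPM and Mirlet7d 3028 ± 693 CPM. The Dlk1-Dio3 locus, an imprinted region of chromosome 12 whose miRNAs are transcribed from the maternal allele, took 6.19% ± 0.123, with 44 of 47 measured members detected. Mir487b led it at 18013 ± 2910 CPM, followed by Mir127 at 6114 ± 1468 CPM, Mir369 at 5268 ± 9.41 CPM and Mir382 at 3760 ± 598 CPM. The miR-17~92 cluster and its paralogs, a proliferation-associated family, took 2.81% ± 0.765. Mir17, in an exon of Mir17hg at chromosome 14, 115043671 to 115043754, had 10296 ± 2605 CPM, against 4920 ± 1142 CPM for Mir93 and 4296 ± 1173 CPM for Mir106b, both within Mcm7 on chromosome 5. Other single genes among the 20 most abundant included Mir335, in an intron of the imprinted gene Mest, at 20707 ± 1935 CPM, and Mir30e, in an intron of Nfyc, at 15960 ± 1110 CPM.

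Neuronal miRNAs together took 1.65% ± 0.0872 of counts, and 17 of 19 measured members were detected. Mir137, at chromosome 3, 118433857 to 118433929, made up most of this share at 9457 ± 193 CPM. Mir128-1, in an intron of R3hdm1, had 1324 ± 604 CPM, Mir138-1 1112 ± 367 CPM and Mir153, in an intron of Ptprn2, 961 ± 0.202 CPM. Neural progenitor miRNAs took 1.08% ± 0.0279, with 7 of 8 measured members detected. Mir135b was the highest of these at 4762 ± 352 CPM, followed by Mir92b at 2498 ± 1.31 CPM. Oligodendrocyte miRNAs took 0.261% ± 0.00946, most of it from Mir219a-2 at 2232 ± 202 CPM, with Mir338, in an intron of Aatk, at 253 ± 104 CPM. Several families of the nervous system have genes with near-identical copies, and reads that fitted several positions, 32.8% ± 0.648 of all reads, were assigned to no gene. The 3 copies of Mir124a, the neuronal miRNA gene family, held means of 22 counts (Mir124a-1), 8.5 counts (Mir124a-2) and 6 counts (Mir124a-3) per library. These copies were singled out after their values were seen. Levels of genes with copies are therefore uncertain, and the ranks describe counts at single positions.

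**Figure D1:**
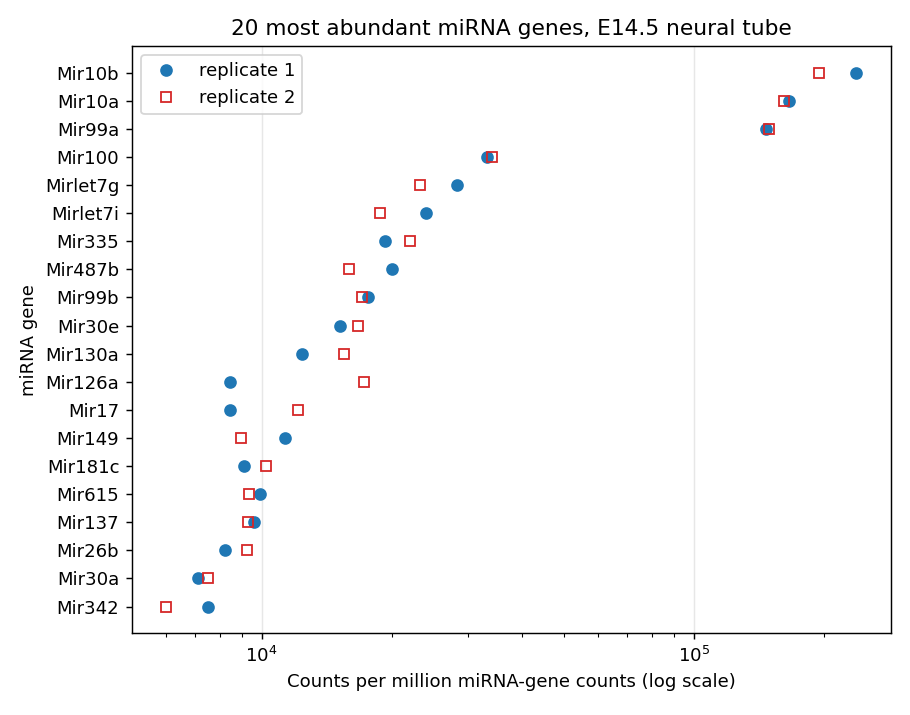
The 20 most abundant miRNA genes (vertical axis), ordered by mean, with each library's CPM on a logarithmic horizontal axis. Filled circles are replicate 1 and open squares replicate 2. Mir10b, Mir10a and Mir99a stand apart at 216129, 163731 and 148255 CPM on average, and of these genes Mir126a shows the widest gap between the libraries on this axis, 8443 against 17271 CPM.

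Lists of miRNAs typical of other cell types were fixed in the same way. The endothelial gene Mir126a, in an exon of Egfl7 at chromosome 2, 26591357 to 26591429, took 1.29% ± 0.624 of counts. The sensory cluster of Mir96, Mir182 and Mir183 on chromosome 6, known from photoreceptors, hair cells and sensory ganglia, took 0.858% ± 0.915. Mesenchymal and cartilage miRNAs took 0.553% ± 0.287, mainly Mir143 at 2686 ± 2259 CPM and Mir140, in an exon of Wwp2, at 2486 ± 255 CPM. In these lists the SD was large because the libraries lay far apart, as described below. The Sfmbt2 cluster families, a rodent placenta-rich group, took 0.291% ± 0.0127, led by Mir467e at 878 ± 53.3 CPM, with 9 of 69 measured members detected and 46 without a count. Reads that fitted several positions entered no gene count, so a member with near-identical copies could lack counts for that reason. Epithelial miRNAs took 0.0458% ± 0.00712, nearly all from Mir203 at 424 ± 71.1 CPM. Multiciliated cell miRNAs took 0.0440% ± 0.00246, with Mir34c at 384 ± 12.6 CPM. The pigment epithelium and choroid plexus list took 0.0322% ± 0.000914, with Mir204, in an intron of Trpm3, at 321 ± 9.43 CPM. Pancreas and endocrine miRNAs took 0.0321% ± 0.00127, with Mir217 at 174 ± 21.3 CPM and Mir375 at 72.9 ± 10.6 CPM.

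The remaining lists were lower. Leukocyte miRNAs took 0.0216% ± 0.00907, with Mir223 at 61.0 ± 58.2 CPM and Mir150 at 59.1 ± 9.18 CPM. Their share was 0.0356% with other-strand reads given to the miRNA gene annotated opposite, an alternative chosen after the data were seen. Pluripotency miRNAs took 0.0163% ± 0.00492, almost all from the Mir302 cluster on chromosome 3, where Mir302d had 59.7 ± 17.6 CPM. Kidney and gut miRNAs took 0.0150% ± 0.00261 and erythroid miRNAs 0.0104% ± 0.00135, the latter with Mir451a, the red cell miRNA, at 76.3 ± 16.9 CPM. Muscle miRNAs took 0.00543% ± 0.000721, with Mir206 at 47.8 ± 5.19 CPM. Some members of this list have copies, and reads that fitted several positions entered no gene count, so the share may be understated. The liver miRNA gene Mir122 stood at 39.7 ± 5.34 CPM, or 0.00397% ± 0.000534. Of the X-linked testis cluster 0 of 20 measured members were detected and 17 had no count in either library. Genes of no list held 39.3% ± 1.84 of counts.

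Counts at single positions were concentrated in few genes. Reads at several positions entered none of the shares below. Of the 1973 miRNA genes, 329 had at least 10 counts in both libraries, 31 in 1 library alone, and 1295 had no count in either. The 10 most abundant genes of each library held 70.8% of its counts in replicate 1 and 65.6% in replicate 2, a mean of 68.2% ± 3.68. Mir10b alone accounted for 21.6% ± 3.01, the 3 highest genes for 52.8% ± 3.10 and the 50 highest for 90.2% ± 1.32. Because shares sum to a whole, a change in Mir10b moves every other share.

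Of the lists compared, sensory and mesenchymal miRNAs differed most between the libraries of the 2 litters and were higher in replicate 2. Mir182 had 3844 counts in replicate 1 and 33631 in replicate 2, 6.52-fold higher after scaling, with a log2 ratio of replicate 1 over replicate 2 of -2.71 (95% interval -2.75 to -2.66). Its cluster neighbours Mir96 and Mir183 were 6.80-fold and 5.20-fold higher, so 3 of 3 sensory members differed. Of the mesenchymal list, 5 of 6 tested members were higher in replicate 2. Mir143, a smooth muscle and fibroblast miRNA gene, was 3.39-fold higher and Mir145a, from the same locus, 2.85-fold higher. Mir214, in an exon of the antisense transcript Dnm3os, was 5.15-fold higher (exact binomial test, Benjamini-Hochberg adjusted p = 9.99e-171), and Mir199b had 18 counts against 254, 10.3-fold higher. The exception was Mir140, the cartilage miRNA gene, at 7312 and 9790 counts with a log2 ratio of 0.00 (95% interval -0.04 to 0.05), or -0.21 with scaling by total counts. The median log2 ratio was -2.71 for the sensory list and -2.06 for the mesenchymal list, each below all 10000 random lists of the same size matched on expression (percentile 0). With counts summed over members, the log2 ratios were -2.62 and -0.90. Of the 6 tested mesenchymal members, 5 were detected in both libraries, with a median of -1.76 (percentile 0). That alternative was added after the data were seen. The 3 sensory genes lie close together on chromosome 6, and Mir143 and Mir145a on chromosome 18, so the members of each list are not all independent.

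The let-7 family and the Hox miRNAs lay on the other side. All 10 tested let-7 genes had a log2 ratio above 0, with a median of 0.72 (percentile 100), and 2 passed the test. Mirlet7c-2 had 1984 counts in replicate 1 and 1035 in replicate 2 (log2 ratio 1.36, 95% interval 1.25 to 1.47), and Mirlet7a-1 had 508 and 320 (log2 ratio 1.09). Both share 20 bases with another miRNA hairpin, so their ratios rest on the reads that fitted a single position. All 6 Hox miRNA genes likewise had ratios above 0, with a median of 0.68 (percentile 100), and 1 passed the test. This was Mir196a-2, in an intron of Hoxc5, with 5042 counts against 2316 (log2 ratio 1.55, 95% interval 1.47 to 1.62). Mir196a-2 has a gene copy in the same list, so its ratio too rests on the reads that fitted a single position. Mir10b had a log2 ratio of 0.50 and Mir10a of 0.25. In the miR-17~92 family 13 of 14 tested genes had ratios below 0, with a median of -0.40 (percentile 0.15), and 0 of 14 passed the 2-fold test. Mir17 stood at -0.31 and Mir20a at -0.44. These 3 medians kept their sign with scaling by total counts, at 0.51, 0.47 and -0.61. The Hox median, 0.50, was within the middle 95% of random lists once gene copies were summed, and so was that of the filter of 100 counts, 0.49.

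Neuronal miRNAs had a median log2 ratio of 0.23 (percentile 99.04), which came to 0.02 with scaling by total counts (percentile 99.09, as all genes moved alike) and to 0.17, within the middle 95%, with copies summed. The 2 neuronal genes that passed the test were Mir128-1, with 5554 and 3291 counts (log2 ratio 1.18), and Mir128-2, with 2370 and 1453 counts (log2 ratio 1.13). Both share 20 bases with another miRNA hairpin, so their ratios too rest on the reads that fitted a single position. With scaling by total counts both fell short of the 2-fold minimum, at 0.97 and 0.92, as did Mirlet7a-1 at 0.88. Neural progenitor miRNAs had a median of 0.21 (percentile 92.64), with 0 of 7 called, and oligodendrocyte miRNAs one of 0.15 (percentile 77.09), which turned to -0.06 with scaling by total counts. The Dlk1-Dio3 miRNAs had a median of -0.06 (percentile 16.26), and 0 of 44 passed the test. Mir126a was 1.77-fold higher in replicate 2 (log2 ratio -0.82) and passed the 2-fold minimum with scaling by total counts, at -1.03.

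The medians of the blood and epithelial lists lay within the middle 95% of random lists, while single members differed. In the leukocyte list, with a median of -0.35 (percentile 19.22), Mir223, the myeloid miRNA gene, was 4.41-fold higher in replicate 2, whereas Mir146, Mir150 and Mir155 had log2 ratios of -0.60, -0.10 and -0.09. With other-strand reads given to the miRNA gene annotated opposite, an alternative chosen after the data were seen, the leukocyte median was -0.60 (percentile 3.6). In the erythroid list, with a median of -0.24 (percentile 25.77), Mir486 was higher in replicate 1 at 56 counts against 23. Mir200c, with 34 and 19 counts, was called in the epithelial list (median 0.23, percentile 74.93), Mir293, with 2 and 14 counts, in the pluripotency list (median -0.39, percentile 20.07), and Mir669h, with 29 and 18 counts, among the Sfmbt2 families (median 0.30, percentile 95.67). With scaling by total counts Mir669h was not called, at a log2 ratio of 0.88. Mir293 and Mir669h were named after their values were seen. The pancreas and endocrine list had a median of 0.19 (percentile 92.4; -0.03 with scaling by total counts) and the multiciliated list one of -0.20 (percentile 32.2), with 0 called in either. Muscle, kidney and gut, liver, endothelial, pigment epithelium and choroid plexus, and X-linked testis lists had fewer than 3 tested members and no median. No gene of the muscle, kidney and gut, liver, or pigment epithelium and choroid plexus lists was called.

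**Figure D2:**
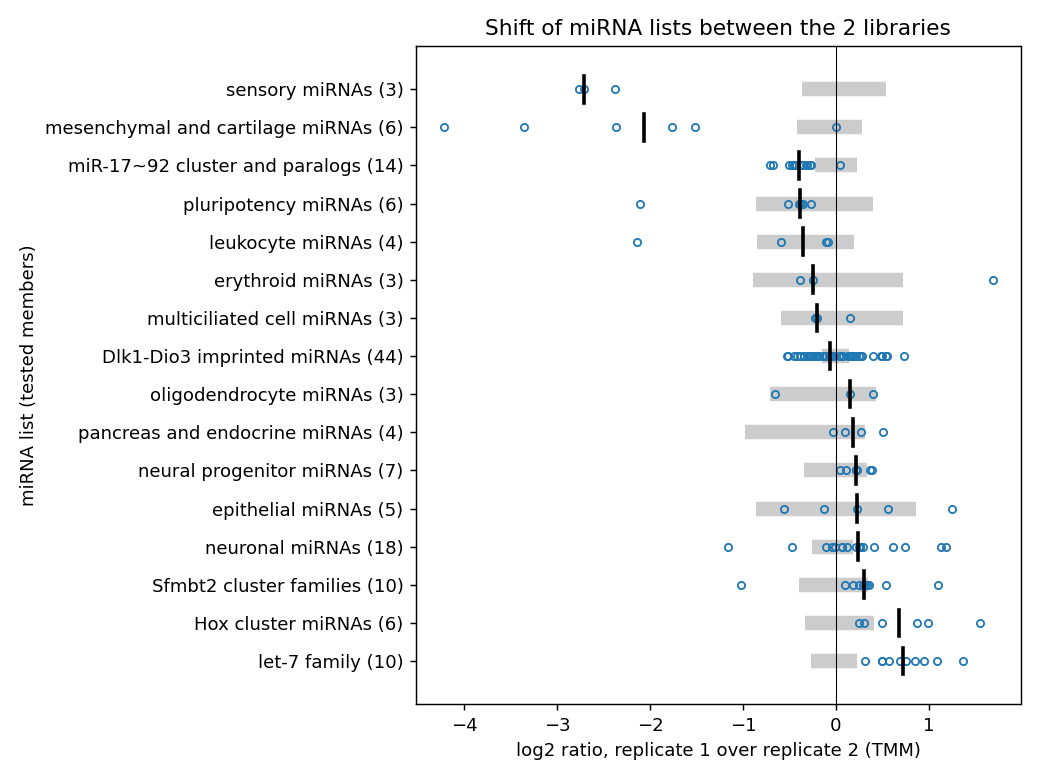
Shift of 16 miRNA lists (vertical axis, number of tested members in parentheses) between the libraries, as the log2 ratio of replicate 1 over replicate 2 after TMM scaling (horizontal axis). Circles are genes, black bars list medians and grey bands the middle 95% of 10000 random lists matched on expression. The sensory and mesenchymal medians lie at -2.71 and -2.06, and those of the Hox miRNAs and the let-7 family at 0.68 and 0.72.

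Over all 360 genes tested, 37 differed between the libraries, 14 higher in replicate 1 and 23 higher in replicate 2 (two-sided exact binomial test, Benjamini-Hochberg adjusted p below 0.05 and at least 2-fold). Adjusted over the list alone, the count of called genes was the same in each of the 22 lists. With scaling by total counts, which moved all log2 ratios by -0.21, the split was 8 and 35, so the share higher in replicate 2 went from 62.2% to 81.4%. Of the 16 lists with a median, 6 lay outside the middle 95% of random lists, 3 on each side, where 0.8 was the number given by chance for independent genes. With 1 library per dam the test compares these libraries, not litters, and has no replicate check. Fewer genes were called once a coefficient of variation of 0.2 between libraries was assumed, and most of those lost were higher in replicate 1. The assumed 0.2 is below the 0.286 (28.6%) estimated from these libraries, so it understates their spread.

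Most genes stayed close between the libraries. Across the 360 genes, log2(CPM + 1) with TMM-scaled library sizes gave Pearson's r = 0.981 (95% interval 0.977 to 0.985) and Spearman's rho = 0.982. This interval treats genes as independent replicates, which they are not, and covers neither counting error nor the spread between litters. The ratio lay within 2-fold for 316 genes (87.8%), and the median absolute log2 ratio was 0.29. Chi-square per degree of freedom between the libraries was 318 over the 329 genes detected in both. The coefficient of variation between the libraries beyond counting noise, from edgeR's common dispersion, was 28.6%.

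**Figure D3:**
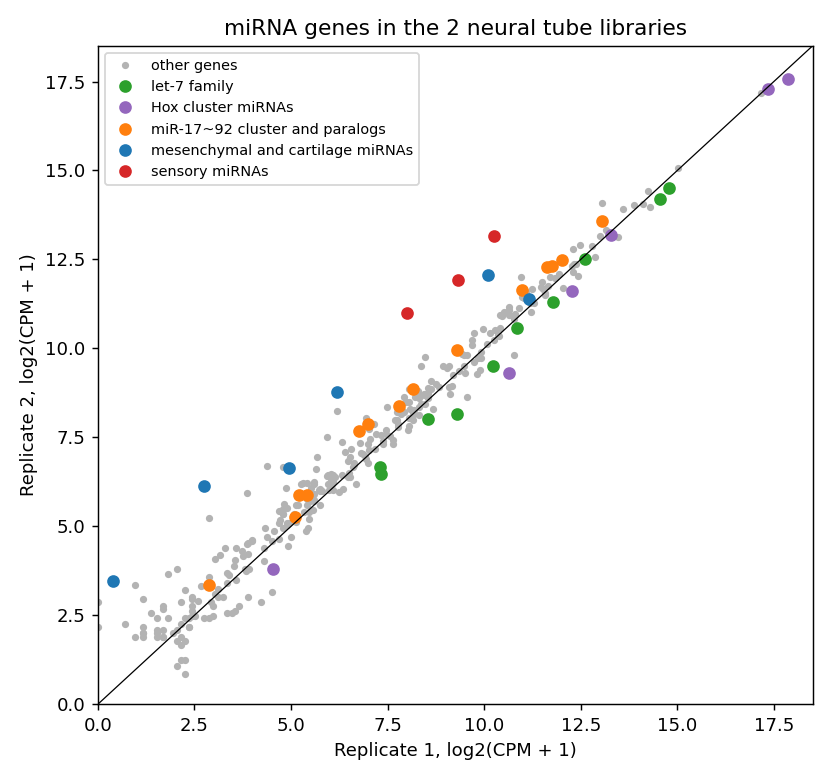
Each miRNA gene in replicate 1 (horizontal axis) and replicate 2 (vertical axis) as log2(CPM + 1), with the line of equal values. Colours mark 5 lists. The sensory genes Mir96, Mir182 and Mir183 lie above the line, with Mir182 at 1212 and 9159 CPM, and most of the 360 tested genes lie close to it.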

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

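The tests of strand and of gene copies in this part were chosen after the results they address were seen.

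Reads on the strand opposite to an annotated miRNA gene were set aside from the main measurement, yet at 16 genes they exceeded in both libraries the limit that a count of 0 allows. At 11 of these they outnumbered the sense reads. Their means, in reads per 1000000 sense counts, were 3296 at Gm25252, 3089 at Gm24321, 2935 at Gm25927, 2118 at Gm24083, 864 at Gm25750, 779 at Gm25301, 381 at Mir299b, 195 at Mir497b, 145 at Mir142b, 57.9 at Gm25641 and 38.4 at Gm24111. These 11 genes held 99.7% of all other-strand reads in each library. A candidate source is the miRNA gene on the opposite strand, for which no value of its own was used here. The annotation places such a gene opposite 100% of the 11, among them Mir376a opposite Gm25252, Mir409 opposite Gm24321, Mirlet7e opposite Gm25927 and Mir191 opposite Gm24083. On this reading the reads would be those of known miRNAs, and the shares of the lists they belong to, such as Dlk1-Dio3 and let-7, would be understated in the main measurement.

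At the other 5 genes the other-strand reads stayed below the sense reads. Their means were 12.4 per 1000000 sense counts at Mir203, 7.34 at Mir3074-1, 2.29 at Mir708, 1.72 at Mir219a-1 and 1.18 at Mir124a-3.

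Reads at several positions made up 32.8% of all reads and entered no gene count. In the let-7, neuronal, neural progenitor and oligodendrocyte lists, 26 members shared 20 bases with another miRNA hairpin and had a median of 993 counts per library, against 6994 counts for the 14 members that shared none. The medians of log2(count + 1) differed by -2.81 (two-sided permutation test, p = 0.00058). Within let-7 the medians were 1067 counts for 5 sharing members and 20497 counts for 5 others. The difference is consistent with reads of the shared members being left out as fitting several places. Copies of a family are not independent, so the p is too small, and a lower expression of these genes stays open, since the counts do not show where the reads left out belong.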

How the results depend on the processing

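Leaving out either library left no ratio to test, so the comparison between the libraries has no replicate check. No paired analysis was possible because there was a single group. Without 1 library, 336 to 353 genes were detected and the top 10 genes held 65.6% to 70.8%. Of 140 list medians under alternatives, 136 stayed on their side of the random lists' limits, and 3, none of them outside those limits, changed sign: oligodendrocyte (-0.06) and pancreas and endocrine (-0.03) with scaling by total counts and epithelial (-0.17) with no filter. Of 478 log2 ratios of named genes, 474 kept their call, 3 lost it, 1 gained it and 19, none of them called, changed sign. These ratios left out the other fold minimums and the assumed coefficient of variation of 0.2, which changed the number of genes called. The coefficient of variation ran from 26.0% to 31.1% over 6 alternatives. Thinned to the smaller library, 328 genes were detected in place of 329, and a count of 0 still allowed 0.946 CPM in replicate 1. With a minimum of 1 count, a looser rule by construction, 530 were detected. The top 10 share was 61.3% with Mir10b left out of the counts. Pearson's r was 0.989 with no filter, 0.975 with a filter of 100 counts, and 0.974 and 0.986 with pseudocounts of 0.1 and 10 CPM. Chi-square per degree of freedom was 198 with no filter, where more genes of few counts entered.

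The 37 differing genes (14 higher in replicate 1, 23 in replicate 2) became 21 with a filter of 100 counts (5 and 16, fewer genes tested), 204 with no minimum fold (105 and 99), 14 with a 4-fold minimum (1 and 13) and 21 with an assumed coefficient of variation of 0.2 (4 and 17). The assumed 0.2 is below the estimated 0.286. Scaling by total counts gave 8 and 35, as it moved all ratios by -0.21.

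Among list medians, the neuronal one, 0.17 with copies summed, and the Hox one, 0.50 with copies summed and 0.49 with a filter of 100 counts, came within the middle 95% of random lists, and the Sfmbt2 one, 0.064 with no filter, left it. The cause was not tested. With members detected in both libraries alone, the mesenchymal median was -1.76, and all 16 lists stayed on their side of the limits.

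With Mir10b out of the denominator, shares rose by construction: neuronal 2.10%, neural progenitor 1.38%, oligodendrocyte 0.333%, let-7 7.66%, Dlk1-Dio3 7.90%, muscle 0.00691%, erythroid 0.0132%, liver 0.00508%, epithelial 0.0582%, pancreas and endocrine 0.0410%, kidney and gut 0.0191%, pigment epithelium and choroid plexus 0.0410%, multiciliated 0.0562%, Sfmbt2 0.371% and X-linked testis 0.000225%. The Hox share, which lost Mir10b, was 22.8%. With other-strand reads given to the gene opposite, an alternative chosen after seeing the data, Dlk1-Dio3 miRNAs took 6.86% and leukocyte miRNAs 0.0356%, as members without a value gained these reads.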

Other observations

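The genes in the next paragraph were chosen after their values were seen. Of the tests below, that of shared hairpins was set before its result was seen, and the others after. The test of GC content and length took the place of a linear correction set before, which explained 0.186% of the variance over 360 genes, left the median at -2.27 and could hardly have moved it.

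Outside the lists, 19 genes differed between the libraries, 13 of them higher in replicate 2. Among these, Mir483, in an intron of Igf2, the fetal growth factor gene, had 228 counts in replicate 1 and 1109 in replicate 2 (log2 ratio -1.86). Mir675, in an exon of the noncoding RNA H19, had 8 and 43 counts (log2 ratio -1.93). On the X chromosome Mir503 had 85 and 372 counts (log2 ratio -1.70) and Mir542 158 and 452 (log2 ratio -1.09), while their neighbour Mir322, with 6300 and 15071 counts, stood at -0.83, under the 2-fold minimum, or at -1.05, past it, with scaling by total counts. Mir152 had a log2 ratio of -1.92, Mir574 of -2.30, Mir221 of -1.38 and Mir27b of -1.06.

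Sensory and mesenchymal miRNA genes were the lists furthest apart between the libraries by their medians, with a log2 ratio at the median of -2.38 over their 9 tested members. A rise of all non-neural tissue alike would lift the other non-neural lists by about as much. Yet the 20 tested members of 7 such lists had a median of -0.064 (bootstrap 95% interval -0.32 to 0.25), and 12 were below 0. The 7 lists were endothelial, erythroid, leukocyte, muscle, epithelial (5 members), liver, and pancreas and endocrine (4 members). The kidney and gut, multiciliated, and pigment epithelium and choroid plexus lists were left out. The interval treats genes as independent, which clustered genes are not. With counts summed, the sensory list stood at -2.62. The mesenchymal list, where Mir140 did not differ, stood at -0.90, close to the endothelial and leukocyte lists at -0.82 and -0.67. A rise of part of the non-neural tissue therefore stays open. The pattern was not carried by shared hairpins (median -2.36 over the 7 members that share none) or by hairpin GC content and length, as the 56 other genes closest to the members in both had a median of 0.052 (bootstrap 95% interval -0.096 to 0.15). Sensory ganglia and connective tissue taken along in the dissection of replicate 2, and a difference between litters, cannot be told apart with 1 library per dam, and the share of members higher there, 88.9% (8 of 9), restates the pattern and favours neither.

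Neighbouring miRNA genes differed between the libraries by similar ratios. Over 333 pairs of 147 genes less than 10000 bases apart on 1 strand, the median absolute difference of log2 ratios was 0.27, below the lowest of 100 shufflings of the ratios, 0.35. Without the Dlk1-Dio3 locus it was 0.25 over 117 pairs, against a lowest shuffling of 0.38. Shared transcripts could set part of the difference between the libraries, as a hypothesis, and the effective number of independent differences may be well below the number of genes called. The shufflings were not matched on expression, so they cannot show how much of the similarity comes from shared transcripts.

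Lower let-7 and higher miR-17~92 levels in replicate 2 may reflect a slightly younger embryo there, as a hypothesis. A younger embryo would also have fewer neuronal miRNAs, and the neuronal median was 0.23 over 18 genes, at percentile 99.04 of random lists, or 0.17 at percentile 95.55, within the middle 95%, with gene copies summed. It would be expected to have more neural progenitor miRNAs, while their median was 0.21 at percentile 92.64, within the middle 95%. Scaling by total counts, which moved all genes alike, put the neuronal and neural progenitor medians at 0.02 and 0.0016. The pluripotency median, -0.39, lay within the range of random lists. The data do not decide this, as each dam has 1 library and both carry the same age label.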
